A study of Homo sapiens with 6 samples.

How the data were processed

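RNA sequencing was analysed for 6 libraries of MDA-MB-231 cells, 3 treated with mitocurcumin at 5 µM for 9 hours and 3 given the DMSO vehicle for the same time. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was captured and stranded libraries were made with a KAPA kit. The genome build was GRCh38, per the submitters' processing notes, and the gene model was RefSeq, per the file headers. The aligner, the counting tool, their versions and whether the counting used strand were not given in the sources used here.

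The deposited raw values were estimated counts per gene and library, not scaled between libraries. This was read from the values, since the totals differed between libraries and only 20.1% to 21.4% of the values above 0 were whole numbers, with fractions as arise when reads that match several genes are shared out. The deposited normalized values were on a log2 scale. Tested against the raw values where above 0, they were log2 of the raw value divided by 1 factor per library. That lower values were set to 0 was assumed and not tested. The table held 58656 gene rows, and 94.8% of the 58546 rows matched by Entrez number had the same start and end as in the RefSeq table used as a reference. It held 0 rows of the mitochondrial chromosome, so mitochondrially encoded mRNAs were not analysed here, and 483 rows of nuclear copies of mitochondrial genes were at 0 in every library. A further 94 rows repeated genes of the pseudoautosomal regions.

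Columns were matched to samples by the treatment word and replicate number in their headings. The heading of mitocurcumin replicate 2 carried a sample number out of sequence with those of the other 5 libraries, and the labels gave no sequencing date or batch. Total counts ran from 23146822 to 29104681 per library. Over all tested genes the biological coefficient of variation was 8.43%. Replicates of the same group differed by more than Poisson sampling, with a chi-square per gene of 5.36 to 19.2, so no library was counted as a duplicate.

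Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16, by its quasi-likelihood F-test with robust dispersion and TMM scaling. Genes were kept by filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 16481. The design had the group as its only term. Fold changes are those edgeR reports, and each SE is the fitted coefficient divided by the square root of its F statistic. P-values were two-sided and were adjusted by the Benjamini-Hochberg method, and a gene counted as higher or lower at an adjusted p under 0.05. The design had assumed whole counts, and the rounding was the step the estimated counts required. CPM values were computed from the rounded counts of the genes kept, with TMM-scaled totals over those genes, and are given as mean ± SD.

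Before the data were examined, 39 gene lists were fixed, of which 38 had at least 3 tested members. They covered redox and stress responses, mitochondria, metabolism, cell death, the cell cycle, inflammation and adhesion. Markers of other cell types were added, and long noncoding RNAs listed as nuclear as a sign of RNA quality. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists. The named genes followed a rule of the same date. It took the 8 genes with the largest rise and the 8 with the largest fall among changed genes with a mean CPM of at least 5 and groups that did not overlap. It added the 2 changed members with the largest change in each list at a mean CPM of at least 1, and 16 genes chosen beforehand whatever their result. Genes named only to spell out a small count were named after their values were seen. Some members of the lists are not reported here by name.

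The test was tried on simulated counts for 16259 genes of this comparison, in which 100 genes changed 1.5-fold and 100 changed 2-fold. It recovered 61% of the former and 83% of the latter. Of its 157 calls 13 were false, a share above the threshold of 0.05 in this single simulation. Fewer genes changed there than were called in the data, which made its adjusted threshold stricter. The recovered shares may therefore understate recovery in the data. The alternatives covered other scalings, other filters, DESeq2 1.42.0, limma voom, limma on the authors' deposited log2 values, a term for the replicate number, each library left out in turn, a stricter threshold, protein-coding genes alone and unrounded counts. The gene lists were also tested with an estimated correlation, with fry and with members at a mean CPM of at least 5.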

Results

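Gene expression was measured by RNA sequencing in MDA-MB-231, an established human cell line of triple-negative breast cancer, which lacks the estrogen and progesterone receptors and HER2 amplification. The cells were given mitocurcumin, a form of the plant polyphenol curcumin modified to accumulate in mitochondria, at 5 µM for 9 hours, or its DMSO vehicle for the same 9 hours. Each group had 3 libraries. The control libraries held 23498132, 25914240 and 23582329 counts, and the mitocurcumin libraries held 24888469, 23146822 and 29104681. The labels call the replicates biological without saying whether they came from separate cultures, so the p-values measure the spread between these samples. Rows of ribosomal RNA took 0.292% to 1.51% of the counts, and the 100 most abundant genes took 14.7% to 16.02%.

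The libraries separated by treatment. The first principal component of log2 CPM held 51.6% of the variance and placed the control libraries between -33.2 and -25.7 and the mitocurcumin libraries between 28.7 and 30.7. On the next component, with 16.2% of the variance, control replicate 1 lay at 31.3, apart from the other control libraries at -17.1 and -17.2. Mitocurcumin replicate 2 stood apart on the fourth component, at -26.4, which held 10.8% of the variance.

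**Figure D1:**
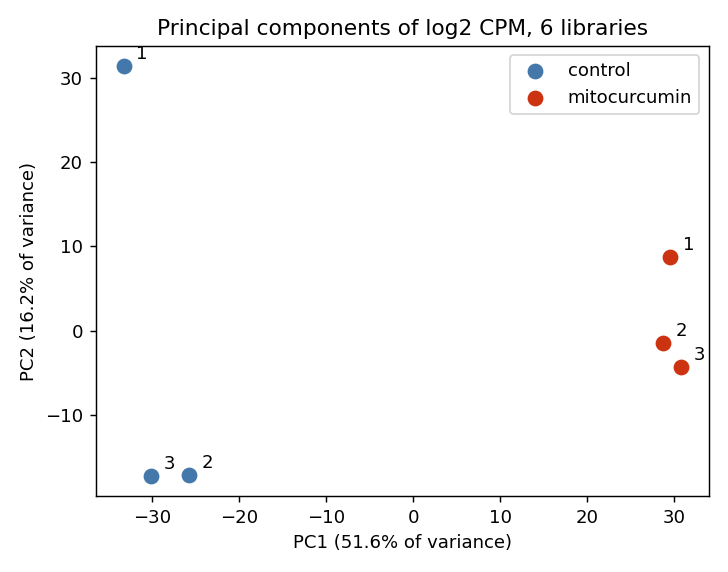
Each point is a library, placed by its scores on principal components 1 (x axis) and 2 (y axis) of log2 CPM, with its replicate number beside it. The mitocurcumin libraries lie between 28.7 and 30.7 on component 1 and the control libraries between -33.2 and -25.7.

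The comparison of mitocurcumin with vehicle asked which transcripts respond to the compound within 9 hours. Target genes of the stress-responsive transcription factor ATF4 rose almost throughout, with TRIB3, CTH and ASNS among the largest increases, and inducible heat shock chaperones such as HSPA6 and HSPA1A rose with them. Genes of DNA replication and mitosis fell broadly by smaller amounts, with CCNE2 and UHRF1 falling most. The immediate early genes FOSB, FOS and EGR1 were among the largest decreases. Subunits of oxidative phosphorylation did not pass the set test as a group.

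Of 16481 genes tested, 2425 were higher and 2938 lower after mitocurcumin at an adjusted p under 0.05, together 5363 or 32.5%. At least a 2-fold change was seen in 568 of them, 371 higher and 197 lower, and at least a 4-fold change in 68 higher and 11 lower genes. The values of the groups did not overlap in 44.9% of tested genes, where chance gives 10% for 3 libraries against 3. Protein-coding genes made up 13880 of the tested rows, with 2175 higher and 2799 lower, and noncoding RNAs made up 1974, with 188 higher and 99 lower.

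**Figure D2:**
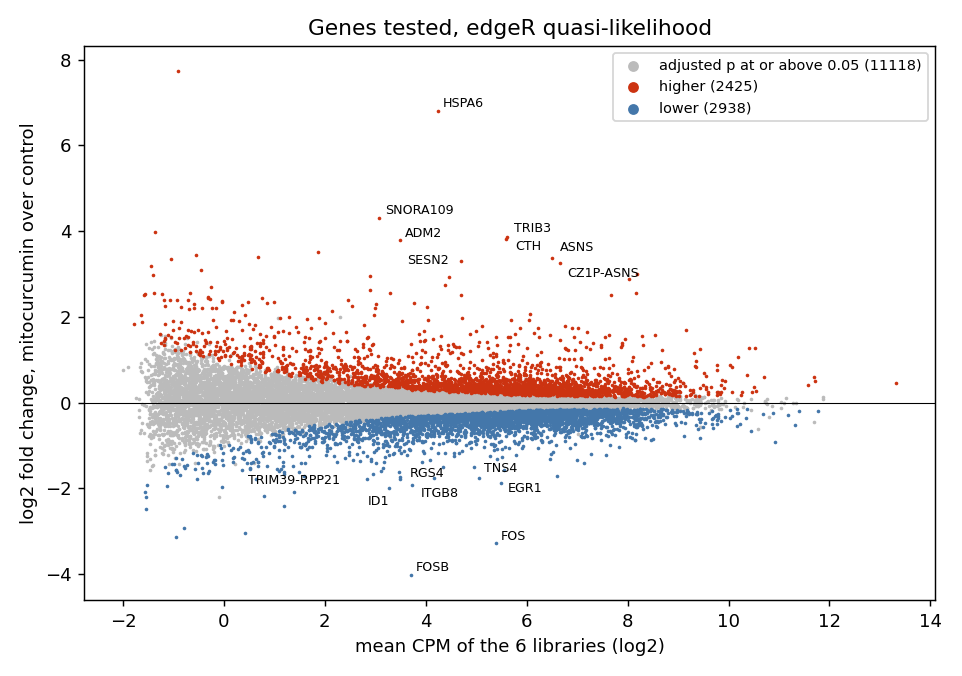
Each point is a tested gene, with its mean CPM over the 6 libraries on a log2 scale (x axis) and its log2 fold change of mitocurcumin over control (y axis). Red points are the 2425 higher genes and blue points the 2938 lower genes by edgeR, and the 16 genes with the largest changes under the naming rule are labelled.

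Changes of single genes are given as log2 fold change ± SE over 3 and 3 libraries, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The largest rise under the naming rule was that of HSPA6, a strictly inducible heat shock protein of the HSP70 family (Entrez 3310, chromosome 1, 161524540 to 161526894, GRCh38). It went from 0.338 ± 0.260 to 37.3 ± 12.3 CPM (SD, n = 3), a change of 6.80 ± 0.49 with an edgeR adjusted p of 7.0e-05. The 3 control libraries together held 24 counts of HSPA6, and without control replicate 3 its change was 7.50. SNORA109, a small nucleolar RNA row (Entrez 106635544, chromosome X, 55183480 to 55183607), rose by 4.31 ± 0.23, and lies 559 bp from a nuclear copy of mitochondrial ribosomal RNA. TRIB3, a pseudokinase induced under stress (Entrez 57761, chromosome 20, 380760 to 397559), rose from 6.28 ± 1.17 to 91.4 ± 5.12 CPM, by 3.86 ± 0.11 (edgeR adjusted p = 2.1e-13). CTH, the enzyme that forms cysteine from cystathionine (Entrez 1491, chromosome 1, 70411268 to 70439851), rose by 3.81 ± 0.10. ADM2, a peptide hormone, rose by 3.79 ± 0.15, and SESN2, a leucine sensor that restrains mTORC1, by 3.31 ± 0.13.

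ASNS, asparagine synthetase (Entrez 440, chromosome 7, 97851677 to 97928441), went from 15.95 ± 0.822 to 166 ± 5.39 CPM, a rise of 3.38 ± 0.07 with an edgeR adjusted p of 2.5e-15. CZ1P-ASNS, with 3.27 ± 0.07, is a readthrough row that overlaps ASNS on the same strand, so the pair may share reads. The largest falls under the naming rule were those of FOSB and FOS. FOSB (Entrez 2354, chromosome 19, 45467996 to 45475179) went from 24.5 ± 7.21 to 1.504 ± 0.509 CPM. FOS (Entrez 2353, chromosome 14, 75278828 to 75282230) went from 75.7 ± 12.3 to 7.81 ± 2.73 CPM. These AP-1 subunits changed by -4.02 ± 0.24 and -3.28 ± 0.22, with edgeR adjusted p-values of 1.4e-08 and 1.1e-05. EGR1, a further immediate early transcription factor, changed by -1.86 ± 0.15, and ID1, an inhibitor of helix-loop-helix transcription factors, fell from 15.5 ± 1.94 to 3.89 ± 0.536 CPM. ITGB8, an integrin subunit, RGS4, a regulator of G protein signaling, and TNS4, a focal adhesion protein, changed by -1.92 ± 0.13, -1.78 ± 0.12 and -1.75 ± 0.10. TRIM39-RPP21, at -1.77 ± 0.16, is a readthrough row whose overlapping gene TRIM39 went the other way, at 0.68.

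**Figure D3:**
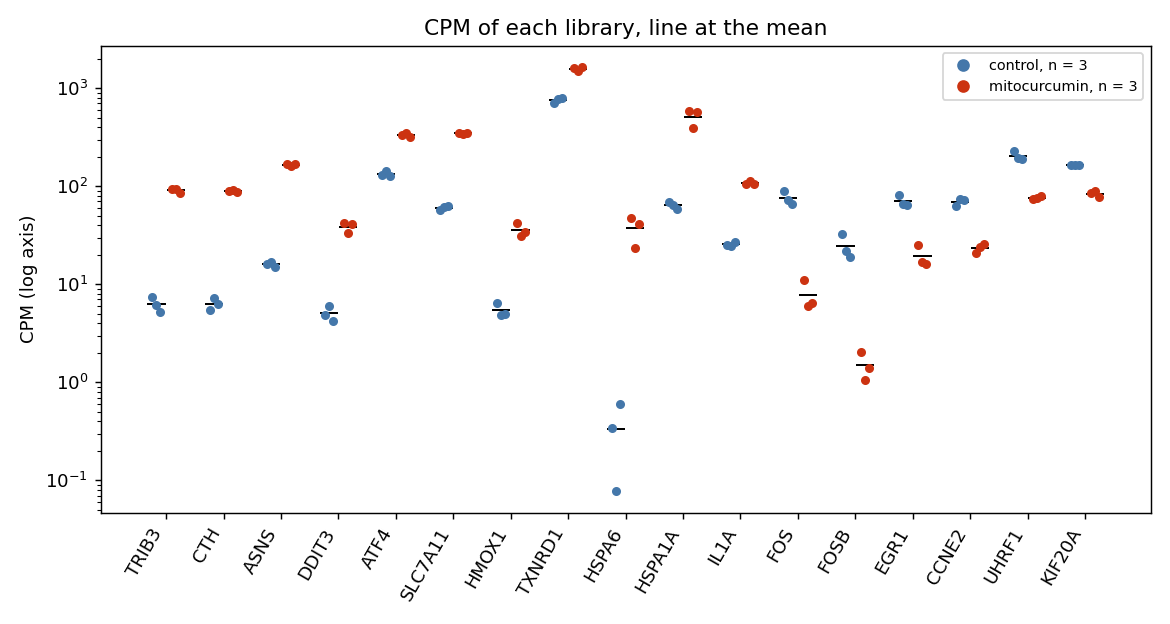
CPM of each library on a log axis (y axis) for 17 genes named in the text (x axis), with control libraries in blue, mitocurcumin libraries in red and a line at each mean of n = 3. Groups do not overlap for any gene shown, and mitocurcumin replicate 2 is the lowest treated library for HSPA6 and HSPA1A.

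ATF4, the transcription factor of the integrated stress response, and its targets formed the group with the clearest rise. Of 38 tested members, 35 were higher and 2 lower, with 35 higher and 2 lower adjusted over the list alone, and the median change was 1.59. ATF4 itself rose by 1.31 ± 0.06, from 135 to 334 CPM. DDIT3, the proapoptotic factor CHOP, rose by 2.94 ± 0.14, ATF3 by 2.56 ± 0.16, CHAC1, a glutathione-degrading enzyme, by 2.96 ± 0.19, and the cytokine GDF15 by 3.50 ± 0.27. The lower members were ATF5, a related transcription factor, and ALDH18A1, an enzyme of proline synthesis. Camera gave an adjusted p of 8.1e-27 for the list, and adjusted p = 0.0501 with an estimated correlation. DDIT3 overlaps MARS1, another member, on the opposite strand.

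Heat shock factor 1 targets, mostly chaperones, rose in 17 of 20 tested members and fell in 0, with the same 17 and 0 adjusted over the list alone. HSPA1A went from 64.3 ± 5.35 to 514 ± 105 CPM, a rise of 3.0 ± 0.17. HSPA1A and HSPA1B are nearly identical in sequence and may share reads. The median change of the list was 0.54, below that of its most inducible members. The set test, camera, gave an adjusted p of 6.9e-10, and adjusted p = 0.302 with an estimated correlation. All 17 risen genes had their lowest treated value in mitocurcumin replicate 2.

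Targets of NRF2, the transcription factor of the oxidative stress response, rose in 17 of 31 tested members and fell in 2, against 17 and 3 adjusted over the list alone. HMOX1, heme oxygenase 1, rose by 2.73 ± 0.14, from 5.43 to 36.1 CPM, and SLC7A11, the cystine transporter, by 2.52 ± 0.06, from 60.4 to 347 CPM. TXNRD1, cytosolic thioredoxin reductase, rose by 1.06 ± 0.06. The lower members were AKR1C1 and AKR1C3, both aldo-keto reductases. Camera gave an adjusted p of 4.1e-04 for the list, and adjusted p = 0.444 with an estimated correlation. Of 29 antioxidant enzyme genes, 9 were higher and GPX3 was lower, with the same 9 and 1 adjusted over the list alone (camera adjusted p = 0.00801, and adjusted p = 0.353 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, rose by 1.25 ± 0.05. The genes TXNRD2, TXN2 and PRDX3, which encode mitochondrial thioredoxin proteins, did not pass the edgeR test, at 0.08 ± 0.19, 0.07 ± 0.10 and 0.09 ± 0.07. PRDX3 passed in 1 of 16 alternatives, without control replicate 1, where its change was 0.18 with an edgeR adjusted p of 0.00375, in a range of 0.00375 to 0.641. TXNRD1 overlaps EID3 on the same strand, and SOD2 overlaps WTAP on the opposite strand.

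Autophagy and lysosome genes of the TFEB list rose in 12 of 27 tested members and fell in 0, with the same 12 and 0 adjusted over the list alone. GABARAPL1 and MAP1LC3B, which encode proteins of the autophagosome membrane, rose by 1.54 ± 0.08 and 1.25 ± 0.05. By camera the list had an adjusted p of 4.6e-04, and adjusted p = 0.285 with an estimated correlation. Ferroptosis-related genes rose in 6 of 14 and fell in 1, NFS1, a cysteine desulfurase, against 6 and 2 adjusted over the list alone. Of the changed members, 5 also belong to other lists, among them CHAC1, HMOX1 and SLC7A11. Its camera adjusted p was 0.0328, with adjusted p = 0.302 with an estimated correlation, and 0.0539 without control replicate 1, in a range of 0.0145 to 0.302 over 10 camera alternatives. Aryl hydrocarbon receptor targets rose in 4 of 8, CYP1B1, AHR, NQO1 and TIPARP, and fell in 0, with the same 4 and 0 adjusted over the list alone. CYP1B1 rose by 0.47 ± 0.07 and AHR by 0.33 ± 0.05. The camera adjusted p of that list was 0.0296, with adjusted p = 0.302 with an estimated correlation. It was 0.0592 without control replicate 1, 0.0733 without control replicate 2 and 0.0658 without mitocurcumin replicate 3, in a range of 0.0158 to 0.302 over 10 camera alternatives.

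Genes of DNA replication and the G1 to S transition fell in 39 of 43 tested members and rose in 0, against 42 and 0 adjusted over the list alone. CCNE2, cyclin E2, went from 69.9 ± 6.35 to 23.7 ± 2.44 CPM, a change of -1.56 ± 0.09, and UHRF1, which guides maintenance DNA methylation, from 205 ± 22.7 to 76.6 ± 2.42 CPM, a change of -1.42 ± 0.07. The median change was -0.50. Camera gave an adjusted p of 6.2e-18, and this was the only one of the 38 preset lists that also passed with an estimated correlation, at adjusted p = 0.0165. Genes of G2 and mitosis fell in 36 of 38 and rose in 0, with the same 36 and 0 adjusted over the list alone and a median of -0.43. KIF20A, a mitotic kinesin, changed by -0.97 ± 0.06 and ASPM, a spindle pole protein, by -0.87 ± 0.08. The camera adjusted p was 7.3e-14, with adjusted p = 0.180 with an estimated correlation.

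Homologous recombination and Fanconi anemia genes fell in 20 of 25 and rose in 0, against 21 and 0 adjusted over the list alone. RAD54L and XRCC2 changed by -0.87 ± 0.09 and -0.79 ± 0.07. The camera adjusted p was 3.0e-08, with adjusted p = 0.239 with an estimated correlation. Tubulin genes fell in 7 of 11 and rose in 0, against 10 and 0 adjusted over the list alone, led by TUBB4B at -0.83 ± 0.07 and TUBB3 at -0.73 ± 0.16. Tubulin paralogs can share reads, and the camera adjusted p was 0.00416, with adjusted p = 0.450 with an estimated correlation. Among 11 cyclins and CDK inhibitors, 2 were higher, CCND2 and CDKN1A, and 5 lower, CDKN2C, CCND3, CCND1, CDK2 and CDKN2D, against 3 and 5 adjusted over the list alone. CCND2 rose by 1.33 ± 0.09 while CCND1 changed by -0.50 ± 0.05 and CDKN2C by -0.87 ± 0.09. CDKN1A, the p21 inhibitor, rose by 0.34 ± 0.09. The list did not pass camera (adjusted p = 0.656), and its median of 0.05 and mean of -0.04 differed in sign. Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, had 1 lower member of 17, H2BC12 at -0.46 ± 0.11, and the same 1 adjusted over the list alone. The camera adjusted p was 0.138, and the list passed without control replicate 3 (0.0485), without mitocurcumin replicate 1 (0.0274) and without mitocurcumin replicate 3 (0.0388), in a range of 0.0274 to 0.444 over 10 camera alternatives.

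NF-kB targets and inflammatory cytokines rose in 17 of 24 tested members and fell in 2, IL11 and CCL2, against 19 and 2 adjusted over the list alone. IL1A, an alarmin cytokine, went from 25.7 ± 1.34 to 109 ± 3.42 CPM, a rise of 2.08 ± 0.07, and CXCL2, a neutrophil chemokine, rose by 1.27 ± 0.08. Camera gave an adjusted p of 2.4e-07, and adjusted p = 0.0675 with an estimated correlation. The immediate early and AP-1 genes went both ways, 7 higher and 10 lower of 30, against 8 and 10 adjusted over the list alone (camera adjusted p = 0.274). FOSB and FOS fell most and ATF3 rose most. Interferon-stimulated genes also went both ways, 7 higher and 4 lower of 25, with the same 7 and 4 adjusted over the list alone (camera adjusted p = 0.947). The lower members were USP18, OAS3, OAS2 and IFIT1. XAF1 rose by 1.53 ± 0.09, while the call of USP18, at -0.84 ± 0.31, was lost in 9 of 16 alternatives. The list's median was -0.07 and its mean 0.03.

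Cytosolic ribosomal protein genes rose by small amounts, 33 higher and 0 lower of 56, against 35 and 0 adjusted over the list alone, with a median of 0.20. RPLP1 and RPS12 rose by 0.50 ± 0.09 and 0.49 ± 0.08. Tested with camera, the list had an adjusted p of 5.6e-07, and adjusted p = 0.444 with an estimated correlation. Reads of these genes may be shared with pseudogenes, which was not measured, and the call of RPLP1 was lost without control replicate 1 (edgeR adjusted p = 0.108, the highest of a range from 5.3e-07). Ribosome biogenesis genes and MYC targets included 5 higher members, MYC, NOB1, POLR1B, RRP12 and WDR43, and 11 lower of 29, against 5 and 13 adjusted over the list alone (camera adjusted p = 0.271). MYC rose by 0.61 ± 0.08 and RRS1, a ribosome assembly factor, changed by -0.60 ± 0.10.

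**Figure D4:**
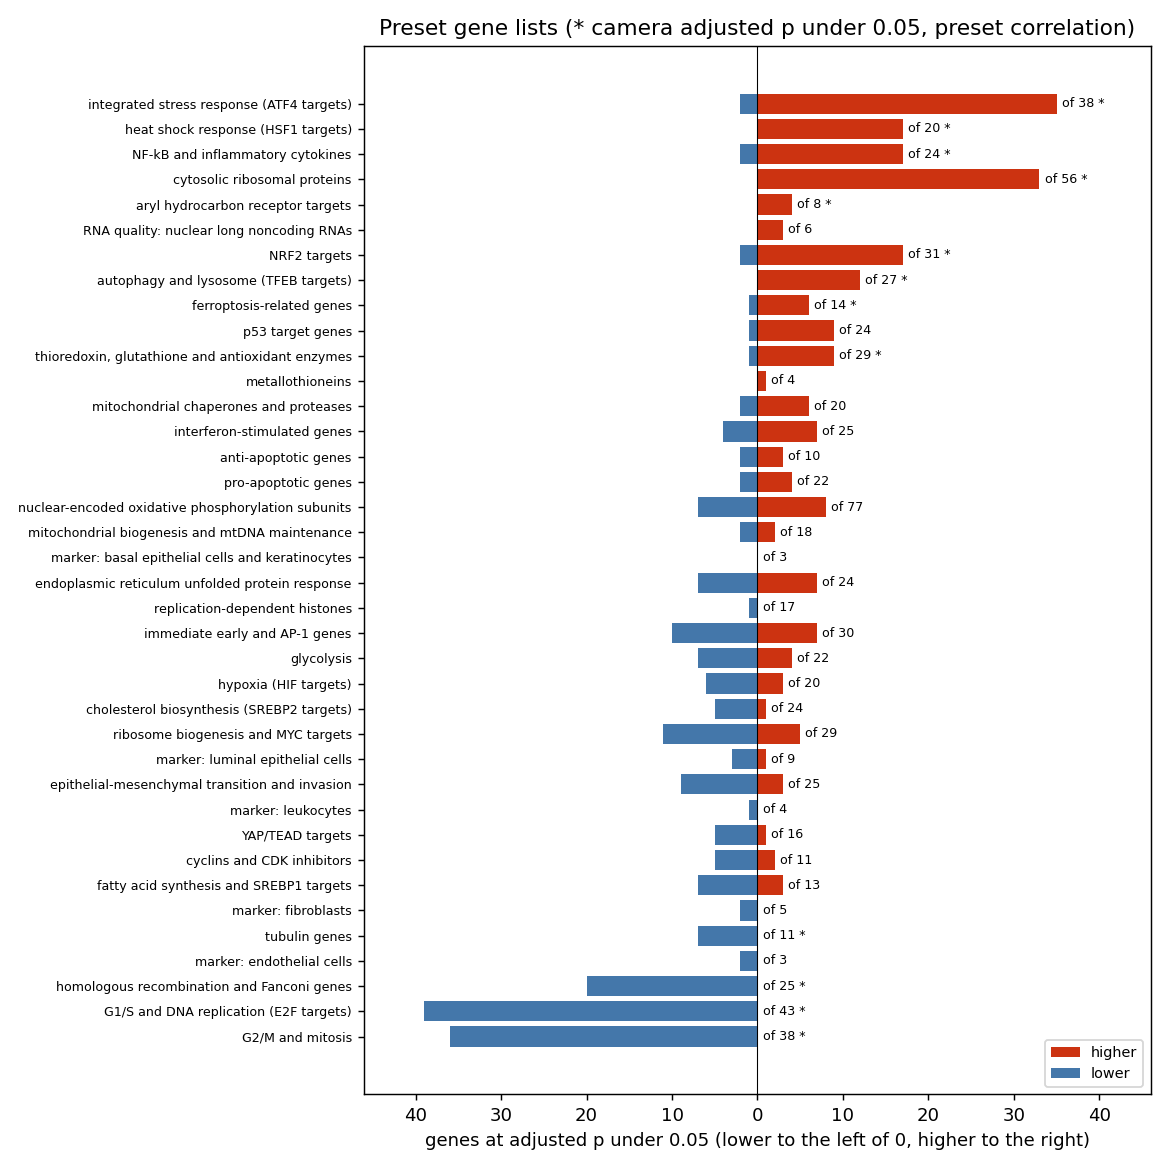
Bars give the number of genes at an adjusted p under 0.05 (x axis) in each of 38 preset lists (y axis), lower genes to the left of 0 and higher genes to the right, with the number tested beside each bar. Stars mark the 13 lists with a camera adjusted p under 0.05 at the preset correlation. Among them are the ATF4 targets with 35 of 38 higher and the G1 to S genes with 39 of 43 lower. Only the G1 to S genes also passed with an estimated correlation.

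Nuclear genes for oxidative phosphorylation subunits had 8 higher and 7 lower members of 77, against 6 and 6 adjusted over the list alone, and a median change of 0.06 (camera adjusted p = 0.271). UQCR11, a complex III subunit, rose by 0.51 ± 0.11 and SDHA, a complex II subunit, changed by -0.45 ± 0.06. Mitochondrial chaperones and proteases had 6 higher and 2 lower of 20, with the same 6 and 2 adjusted over the list alone (camera adjusted p = 0.274). HSPA9, mortalin, rose by 0.61 ± 0.07 and its exchange factor GRPEL2 by 0.55 ± 0.08, and the lower members were SPG7 and TRAP1. Mitochondrial biogenesis genes had 2 higher, TFB1M and TFB2M, and 2 lower, PPRC1 and NRF1, of 18, the same adjusted over the list alone (camera adjusted p = 0.764). TFB1M, a methyltransferase of mitochondrial ribosomal RNA, rose by 0.51 ± 0.12 and PPRC1, a coactivator related to PGC-1, changed by -0.56 ± 0.09.

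Glycolysis genes had 4 higher members, SLC16A1, SLC2A3, HK1 and PGK1, and 7 lower of 22, against 4 and 8 adjusted over the list alone (camera adjusted p = 0.439). SLC16A1, a lactate transporter, rose by 2.40 ± 0.21, and SLC2A3, a glucose transporter, by 0.84 ± 0.07. The median of the list was -0.09 and its mean 0.02. Hypoxia genes had 3 higher, MXI1, BNIP3 and BNIP3L, and 6 lower of 20, the same adjusted over the list alone, with ANGPTL4 at -1.30 ± 0.18 and EGLN3 at -1.18 ± 0.11 (camera adjusted p = 0.274). Cholesterol synthesis genes had 1 higher, INSIG1, and 5 lower of 24, against 1 and 4 adjusted over the list alone (camera adjusted p = 0.236). IDI1, an isomerase of the pathway, changed by -0.61 ± 0.07. Fatty acid synthesis genes had 3 higher, ME1, LPIN1 and SCD, and 7 lower of 13, against 4 and 8 adjusted over the list alone, led by FASN at -0.62 ± 0.10 and ELOVL6 at -0.57 ± 0.06 (camera adjusted p = 0.236).

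The endoplasmic reticulum unfolded protein response list split, with 7 higher and 7 lower of 24, against 8 and 7 adjusted over the list alone. HERPUD1 and DNAJB9, both of endoplasmic reticulum protein quality control, rose by 1.74 ± 0.09 and 1.63 ± 0.08. The median was -0.07, the mean 0.20 and camera's direction upward (adjusted p = 0.386). The p53 targets had 9 higher and 1 lower, ZMAT3, of 24, against 9 and 3 adjusted over the list alone (camera adjusted p = 0.155). The largest rises there were in GDF15 and SESN2, which both belong to the ATF4 list as well. Among 22 proapoptotic genes, 4 were higher, BBC3, TNFRSF10B, BAK1 and PMAIP1, and 2 lower, APAF1 and TNFRSF10A, the same adjusted over the list alone (camera adjusted p = 0.430). BBC3, the BH3 protein PUMA, rose by 2.34 ± 0.27, from 0.653 to 3.35 CPM, TNFRSF10B, a death receptor, by 0.58 ± 0.05, and PMAIP1, the BH3 protein NOXA, by 0.18 ± 0.06. The call of PMAIP1 was lost without control replicate 2 (edgeR adjusted p = 0.0717) and without mitocurcumin replicate 3 (0.0948), in a range of 0.00639 to 0.0948. Among 10 antiapoptotic genes, 3 were higher, BCL2L2, BIRC2 and CFLAR, and 2 lower, BCL2 and BIRC5, against 5 and 2 adjusted over the list alone (camera adjusted p = 0.329). MCL1, at 0.12 ± 0.05, did not pass (edgeR adjusted p = 0.0689), but passed in 5 of 16 alternatives, with a range of 0.0264 to 0.181. BCL2, at -0.30 ± 0.11, passed narrowly (edgeR adjusted p = 0.0497) and was lost in 12 of 16 alternatives, with a range of 0.0149 to 0.215. BCL2L2, at 0.38 ± 0.10, overlaps the readthrough row BCL2L2-PABPN1 on the same strand.

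Epithelial-mesenchymal transition and invasion genes had 3 higher and 9 lower of 25, against 4 and 9 adjusted over the list alone (camera adjusted p = 0.271). CDH11, a mesenchymal cadherin, changed by -1.04 ± 0.05, and VIM, vimentin, did not pass, at 0.11 ± 0.05 (edgeR adjusted p = 0.0900), but passed in 5 of 16 alternatives, with a range of 0.0298 to 0.199. YAP/TEAD targets had 1 higher, AJUBA, and 5 lower, CCN2, F3, ARHGEF17, AMOTL1 and TEAD1, of 16, the same adjusted over the list alone (camera adjusted p = 0.168). CCN2, a matricellular protein, changed by -0.98 ± 0.05 and AJUBA, a LIM domain protein, rose by 0.80 ± 0.06. Of 4 tested metallothioneins, MT1E was higher, at 0.59 ± 0.12, with the same 1 adjusted over the list alone (camera adjusted p = 0.764).

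Markers of other cell types did not pass camera as groups. Luminal epithelial markers had 1 higher, XBP1, and 3 lower, GATA3, KRT19 and KRT8, of 9, the same adjusted over the list alone (camera adjusted p = 0.674), with a median of -0.15 and a mean of 0.05. XBP1, also a factor of the unfolded protein response, rose by 1.23 ± 0.06. The 3 basal markers did not pass the edgeR test, nor adjusted over the list alone, with LAMB3 at 0.11 ± 0.08, COL17A1 at -0.23 ± 0.11 and TP63 at -0.26 ± 0.26 (camera adjusted p = 0.725). The lower fibroblast markers were COL1A2 and ACTA2, 2 of 5, the same adjusted over the list alone (camera adjusted p = 0.271). CD68 was the 1 lower leukocyte marker of 4, against 2 adjusted over the list alone (camera adjusted p = 0.160), and the 2 lower endothelial markers of 3 were PECAM1 and KDR, the same adjusted over the list alone (camera adjusted p = 0.274). The calls of ACTA2 and KDR were lost in 6 and 4 of 16 alternatives. Of 6 long noncoding RNAs listed as nuclear and as a sign of RNA quality, 3 were higher, NEAT1, GAS5 and SNHG5. The same 3 were higher adjusted over the list alone, with 0.65 ± 0.07 for NEAT1 and 0.55 ± 0.07 for GAS5. GAS5 and SNHG5 also host small nucleolar RNAs, so their rise need not mark RNA quality. The camera adjusted p was 0.0631, and the list passed without control replicate 2 (0.0424) and without mitocurcumin replicate 2 (0.0479), in a range of 0.0424 to 0.444 over 10 camera alternatives.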

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

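The analysis of unrounded counts was chosen after seeing the data, and the other settings were fixed before. The number of genes changed at an adjusted p under 0.05 was 5363 as reported. It lay between 4100 and 6088 when each library was left out in turn and between 3654 and 5806 under the other settings, the lowest at an adjusted p under 0.01. Genes changed at least 2-fold numbered 451 to 659 against 568. DESeq2 called 5099, limma voom 5296 and unrounded counts 5317. None of the 5363 genes called as reported was called in the opposite direction under any of the 16 settings that refitted all genes. Of 1456 values of the 91 named genes under these settings, 1401 stayed on their side of the threshold, 44 lost the call, 11 gained it and 0 reversed. The lost and gained calls fell on 10 genes.

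The set tests passed in 13 lists as reported, in 1 with an estimated correlation and in 29 with fry. Fry's p-value asks whether a list's genes move, on balance, one way, and does not compare them with other genes. Leaving out each library in turn gave 11 to 14 lists. Over all settings 378 of 415 list results stayed on their side of the threshold, and 0 reversed.

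Same-numbered libraries showed little common deviation (r of 0.10, 0.02 and -0.01 across genes, which are not independent replicates). Pairs of a control and a mitocurcumin library with different numbers ran from -0.11 to 0.09. The pair of replicate 1 was thus the highest, and a small deviation shared by these libraries stays open. The replicate numbers were not taken to pair the samples. With a replicate block the count was 5806, the highest of the settings that kept all 6 libraries, and 5342 of these were among the 5363. The block changed no call of a named gene or list, and not every library correlated best with its own number. The planned pseudocounts and filters for values other than counts were not run, since the values were counts. At this depth the simulated test recovered 61% of 1.5-fold changes. The simulation held fewer changed genes than were called in the data, which made its adjusted threshold stricter. Recovery in the data may therefore be higher, but genes without a call are still not shown to be unaffected.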

Other observations

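The tests on heat shock genes in mitocurcumin replicate 2 and on SNORA109 were chosen only after the result was seen. The same holds for the synthetases without members of the ATF4 list or without GARS1 and KARS1. It also holds for the full list of small nucleolar RNA hosts. The 7 further lists were chosen after the data were examined and before they were tested as lists.

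Aminoacyl-tRNA synthetases of the cytosol, which charge tRNAs for translation, rose in 13 of 20 tested genes and fell in 3, RARS1, VARS1 and FARSA. GARS1 and KARS1 on this list also encode the mitochondrial enzyme. The median change was 0.85, with a camera adjusted p of 1.6e-06 over the 7 added lists, and adjusted p = 0.0340 with an estimated correlation. Of 17 enzymes for mitochondrial translation, 1 was higher, VARS2, and 4 were lower, with a median of -0.04. The medians differed by 0.89 (two-sided permutation test of the list labels over genes, p = 0.00279), and by 0.89 without GARS1 and KARS1 (permutation p = 0.00188). Of the cytosolic enzymes, 6 belong to the ATF4 list. Without them 7 of the other 14 were still higher, but the difference in medians was 0.22 with a permutation p of 0.0631. The contrast thus rests in part on members of the ATF4 list. Whether ATF4 also acts on the other cytosolic enzymes was not tested.

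Proteasome subunits had 5 higher and 2 lower genes, PSMC6 and PSMA3, of 31 and did not pass camera (adjusted p = 0.207). The TCP1 ring chaperonin, a folding machine for actin and tubulin, had 2 higher genes of 8, TCP1 and CCT4 (camera adjusted p = 0.237). Long noncoding RNAs that host small nucleolar RNAs had 6 higher and 2 lower, SNHG12 and SNHG3, of 13 (camera adjusted p = 0.229). That list left out the hosts GAS5, SNHG1 and SNHG5, of which GAS5 and SNHG5 were higher. With them 8 of 16 were higher (camera adjusted p = 0.0694, and adjusted p = 0.483 with an estimated correlation). Mitochondrial ribosomal proteins had 4 higher, MRPL54, MRPS16, MRPL30 and MRPL45, and 4 lower, MRPL16, MRPL17, MRPS2 and MRPL19, of 77, with a camera adjusted p of 0.790.

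The grouping by treatment gave 5363 changed genes by edgeR. Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 6787 genes and the others 140 to 509. Each of the others mixed treated and control libraries, so the treatment effect widened the spread within their groups. Their counts therefore do not show what libraries without an effect would give. With 10 splits a share under 0.05 cannot be reached.

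The small rise of cytosolic ribosomal protein mRNAs, with a median of 0.20, was weighed against transcript length, since these mRNAs are short. In 10000 lists of other genes matched on length and CPM, the median reached 0.0907 at the upper bound of the central 95% and 0.17 at most, which argues against length alone. A candidate explanation is a joint rise of mRNAs that begin with a terminal oligopyrimidine tract, which ribosomal protein mRNAs share. The 21 listed mRNAs of that class that are not ribosomal proteins had a median of 0.17, with 11 higher and 1 lower, HNRNPA1 (camera adjusted p = 0.00417, and adjusted p = 0.164 with an estimated correlation). Reads shared with pseudogenes stay open.

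Heat shock genes were weaker in mitocurcumin replicate 2, where all 17 risen genes had their lowest treated value. Their log2 changes from the control mean, summed over genes, were there 81.5% of the mean of the other treated libraries. For the ATF4 targets this share was 97.6%, a difference of 16.1 percentage points (95% bootstrap interval over genes 12.7 to 21.8). In that library the ATF4 targets thus lay closer to the other treated libraries than the heat shock genes did. The interval resamples genes within 1 library, which are not independent, and does not measure variation between libraries. The heat shock genes were also tested because they were seen to be lowest there. The test therefore cannot decide whether the response of that library was weaker throughout. A smaller weakening of the ATF4 targets stays open, since 18 of 34 of them were also lowest in that library. Their share computed in the same way was 98.2% for mitocurcumin replicate 3, close to that of replicate 2, and 104.3% for replicate 1. For the heat shock genes these shares were 108.5% and 111.9%. A different handling or sequencing run of that library, whose sample number was out of sequence, and culture-to-culture variation in the heat shock response may both account for it and cannot be separated with 1 library.

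SNORA109 rose by 4.31 ± 0.23 from 0.803 to 16.1 CPM. The row is 128 bp long and lies 559 bp from MTRNR2L10, a nuclear copy of mitochondrial 16S ribosomal RNA with 80.4% identity to it. Reads of mitochondrial ribosomal RNA could be assigned there, and a transcript of this locus could also have risen. The 483 rows of nuclear mitochondrial copies were at 0 in every library, and the sequence of the row itself was not used here, so the sources cannot be told apart.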
